A study of Danio rerio with 6 samples.

How the data were processed

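RNA of sorted cells was sequenced from 6 libraries, 3 control and 3 exposed to bisphenol A (BPA). Per the labels, the embryos carried a transgene that expresses green fluorescent protein (GFP) under the control of sp7, an osteoblast transcription factor gene. Also per the labels, the exposed arm received 200 nM BPA from 24 hours post fertilization, GFP-positive cells were collected at 4 days post fertilization, and each arm held 400 embryos. The labels do not say whether the 3 libraries of an arm came from separate pools of embryos, so the spread behind each p value may be technical. They state that stocks were made in dimethyl sulfoxide and do not state what the control medium held. The series' protocols name other chemicals and fish lines, which were not analysed here.

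The deposited table holds raw read counts per Ensembl gene for 32520 genes, with no normalization. Per the submitters' processing notes, FastQC, STAR 2.7.10a, featureCounts 2.0.6, R 4.4.2 and the zebrafish build GRCz11 were used; the notes give no order, options, strand setting or annotation release. Between 76.1% and 81.7% of the nonzero counts in each library were even, so both mates of a read pair appear to have been counted, and the counts then overstate the number of fragments. Whether reads that fit more than 1 gene were counted, and whether strand was used, is not stated. Genes with a near-identical copy, and genes that overlap another, are therefore uncertain.

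Gene names came from a table of gene identifiers and symbols that covered 29201 of the 32520 genes and left 3319 without a name. Symbols are printed as that table gives them; many are in upper case and a few are carried by more than 1 gene. A RefSeq table of another zebrafish assembly (GRCz12tu) was used for synonyms and for the order of genes only. Of the matches between fixed list symbols and genes, 592 were by symbol, 170 through a symbol that stands without its paralog letter, and 7 by synonym, while 42 symbols had no match. A symbol without its paralog letter can bring in up to 3 genes, each of which then counts as a member. No coordinates are given, and no check of GC content or gene length was possible without a genome of the build used.

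Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, statmod 1.5.0). Genes with low counts were removed with filterByExpr by group at its defaults (minimum count 10, minimum total count 15), libraries were scaled by the trimmed mean of M values (TMM), and a robust quasi-likelihood F-test compared the exposed with the control group. P values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are given as CPM, which are counts scaled to a common library size with the TMM factors, with the standard deviation (SD) over n = 3 libraries. Log2 fold changes are exposed against control. The standard error (SE) beside each one is that of the difference of mean log2 CPM over the replicates. Where every library of a group was at 0, folds are lower bounds against a floor of 3 counts per library; where a group held 1 to 3 counts in all, the ratio is given with an exact 95% conditional binomial interval. Such intervals and floors cover at most counting error, since reads without molecular identifiers are not independent molecules. If both mates of a pair were counted, the intervals are also too narrow and the floors too low.

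The following 35 lists were tested with limma's camera, two-sided, at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and p values were adjusted over the lists: osteoblast lineage and bone matrix, RANKL-OPG and osteoclast, endocannabinoid system, estrogen and estrogen-related receptor axis, xenobiotic metabolism, NRF2 and oxidative stress, Wnt signaling, BMP and TGF-beta signaling, Hedgehog signaling, cell cycle, p53 and apoptosis, unfolded protein response, immediate early and dissociation stress, inflammation, cholesterol synthesis, PPAR and lipid handling, extracellular matrix remodelling, mitochondrially encoded genes, cytosolic ribosomal proteins, and markers of chondrocytes, skeletal muscle, epidermis, neurons, photoreceptors, lens, erythroid cells, leukocytes, liver, exocrine pancreas, intestine, endothelium, pigment cells, tendon and fibroblasts, otic vesicle, and neural crest and glia. Camera compares a list with all other tested genes. Some single genes are not reported here, though the tests and list counts include them. Values per library, such as shares of counts, were compared with a two-sided exact permutation test, whose smallest p with 3 against 3 libraries is 0.1.

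The lists, the tests of the comparison and the rule for named genes were fixed before the data were examined; what was added or changed later is named where it appears. The rule for named genes took, among genes past the threshold with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a clone name, the 10 with the largest increase and the 10 with the largest decrease. It added up to 4 members of each list by smallest p. It also took 20 genes of bone, cannabinoid and estrogen biology in any case, all of which were matched. Some were matched only through a symbol without its paralog letter, which may belong to another paralog (esr2a and esr2b through ESR2, cyp19a1b through CYP19A1). The rule gave 170 genes, of which 166 could be tested. Clone names passed over were 4 among the increases and 2 among the decreases.

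The procedure was tested on simulated data before use. Counts were drawn for 21194 genes from the means and library sizes of the real libraries, with 200 genes changed, and 20815 genes were left after the low-count filter. Among the changed genes left, the test recovered 67.7% of those changed 2-fold and 49.5% of those changed by 0.5 on the log2 scale. Of its 120 calls 7.5% were false, all recovered genes had the right sign, and 0 genes were called when none was changed. Far fewer genes were changed than were called in the data (8213), so scaling and error control at that extent were not tried. On 21194 genes, a list of 25 genes raised by 0.5 on the log2 scale gave a list test p of 2.37e-22. The smaller p of the random lists was 0.0974. Genes were drawn independently of each other, so the list test was not tried on lists whose genes vary together.

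Alternatives were other scalings (relative log expression, library size only, upper quartile), DESeq2 1.42.0, limma-voom, no low-count filter and a stricter one (a mean of at least 10 counts in each group and 50 overall), no robust estimation, an adjusted p threshold of 0.1, a fold threshold of 2, the replicate number as a block, and leaving out each library. For the lists they were an estimated correlation and the fry rotation test. Halved counts, and leaving out ribosomal protein and mitochondrially encoded genes, were added after the data were seen.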

Results

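The data are RNA sequencing counts of GFP-positive cells sorted from sp7 reporter zebrafish at 4 days post fertilization. There were 3 libraries from control embryos and 3 from embryos exposed to 200 nM BPA, a chemical with estrogenic activity. The reporter marks cells that express sp7, which osteoblasts need to differentiate. Control libraries 1, 2 and 3 held 37716680, 43403568 and 32173615 counts, and exposed libraries 1, 2 and 3 held 30748435, 42207786 and 42863847. A mean of 23014 ± 207 genes (SD, n = 3) had a count above 0 in the control libraries and 24112 ± 171 in the exposed libraries; after thinning to the smallest total the means were 22975 and 24031 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The series title names bone loss, osteoporosis and the endocannabinoid receptor as its subject, and the comparison of the groups asks which transcripts differed in the sorted cells after exposure.

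As lists fixed beforehand, inflammation, leukocyte, cholesterol synthesis and immediate early and dissociation stress genes were higher in the exposed libraries, and liver, intestine, photoreceptor, neural crest and glia, endothelium and BMP and TGF-beta genes were lower, each at a camera adjusted p of 0.046 with an estimated correlation. Among single genes, the antiviral GTPase gene mxc rose from 1.72 ± 0.428 to 39.2 ± 2.23 CPM (SD, n = 3 per group), the cytokine gene il1b from 4.19 ± 0.65 to 28.9 ± 1.37 CPM, and the epidermal keratin gene krt5 from 1480 ± 8.66 to 3582 ± 94.4 CPM. The metallothionein gene MT1X, whose product binds metals, fell from 119 ± 1.57 to 15.4 ± 0.874 CPM, and fabp10a, a liver fatty acid binding protein gene, from 675 ± 29.7 to 158 ± 3.60 CPM. Bone genes moved in both directions, and SP7 itself did not pass the test. Of 21194 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 8213 passed an adjusted p of 0.05, of which 4255 were higher and 3958 lower in the exposed libraries. Among them 1926 changed at least 2-fold, 1185 up and 741 down. The values of the groups did not overlap for 10249 genes, or 48.4% of those tested, where chance gives 10%. Replicates were close, with correlations of log2 CPM across genes between 0.963 and 0.984 within a group and between 0.944 and 0.951 across groups; genes are not independent replicates. The common biological coefficient of variation was 0.141.

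The largest increases among genes of at least 1 CPM included immune genes. The Mx gene mxf (ENSDARG00000026049) had 0, 0 and 2 counts in the control libraries and 404, 544 and 598 in the exposed libraries. This is a ratio of 759 with a 95% interval of 210 to 6275. The interval, like that of the next gene, is too narrow if both mates of a pair were counted. The log2 fold change of mxf was 9.32, 8.70 without control library 2 and at least 7.49 against the floor without control library 3. The granulin gene grna.2 had 3 control counts in all against 453 in the exposed libraries, a ratio of 148 with an interval of 50.4 to 722 (log2 fold change 7.05, or 7.78 without control library 2). ACOD1, which makes the antimicrobial metabolite itaconate in macrophages, rose from 0.0951 ± 0.0789 to 8.32 ± 0.717 CPM, with 2, 2 and 6 control counts (log2 fold change 6.50 ± 0.42 SE, adjusted p = 2.68e-15; 7.31 without control library 3). The immunity-related GTPase gene irge1 rose from 0.0358 ± 0.0321 to 2.21 ± 0.384 CPM, with 0, 2 and 2 control counts. The macrophage transcription factor gene SPIC rose from 0.0827 ± 0.143 to 2.54 ± 0.308 CPM, with 0, 0 and 8 control counts (log2 fold change 5.06, 4.4 without control library 2 and at least 5.09 without control library 3). The chemokine gene cxcl19 rose from 0.149 ± 0.163 to 2.64 ± 0.834 CPM, with 12, 0 and 4 control counts (log2 fold change 4.16, 5.53 without control library 1 and 3.51 without control library 2). Among the other large increases were those of plekhs1.1 (1.07 to 16.9 CPM) and the cytochrome P450 gene cyp2aa3 (0.158 ± 0.198 to 2.43 ± 0.957 CPM, with 1, 17 and 2 control counts; log2 fold change 3.83, or 5.71 without control library 2). All of these calls held without any 1 library.

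The largest decreases were in genes of several tissues. The yolk protein gene vtg7, a vitellogenin, fell from 2.87 ± 0.786 to 0.0317 ± 0.055 CPM, with 4 counts in the exposed libraries (log2 fold change -6.26 ± 0.54 SE, adjusted p = 2.90e-09). All 4 lay in exposed library 2; without it the log2 fold change was -5.10 or lower, and without exposed library 3 it was -5.66. The metabolic enzyme genes cyp39a1 and tdo2b, which act on oxysterols and on tryptophan, fell by 3.33 and 3.13 on the log2 scale. The insulin-like growth factor binding protein gene igfbp1b (ENSDARG00000038666) fell from 47.0 ± 0.424 to 5.40 ± 0.605 CPM. The Notch target gene her4.1 fell from 10.9 to 1.32 CPM, the natriuretic peptide gene nppcl2 from 5.17 to 0.635 CPM, and the cone phosphodiesterase subunit gene PDE6H from 7.18 to 1.01 CPM. The neuropeptide gene gnrh3 fell from 2.41 ± 1.41 to 0.280 ± 0.213 CPM (log2 fold change -3.06, or -3.88 without exposed library 2) and bicc2 from 3.20 to 0.414 CPM. MT1X (ENSDARG00000041623) fell by 2.95 ± 0.05 on the log2 scale (adjusted p = 2.86e-25). In all, 154 of the 170 named genes passed the threshold, and for 153 of these the 3 exposed values lay outside the range of the 3 control values, with spp1 the exception. The rule for named genes asked for no overlap or took the smallest p, so the choice of genes largely fixed this. Among all 8213 called genes, 7855 had no overlap.

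**Figure D1:**
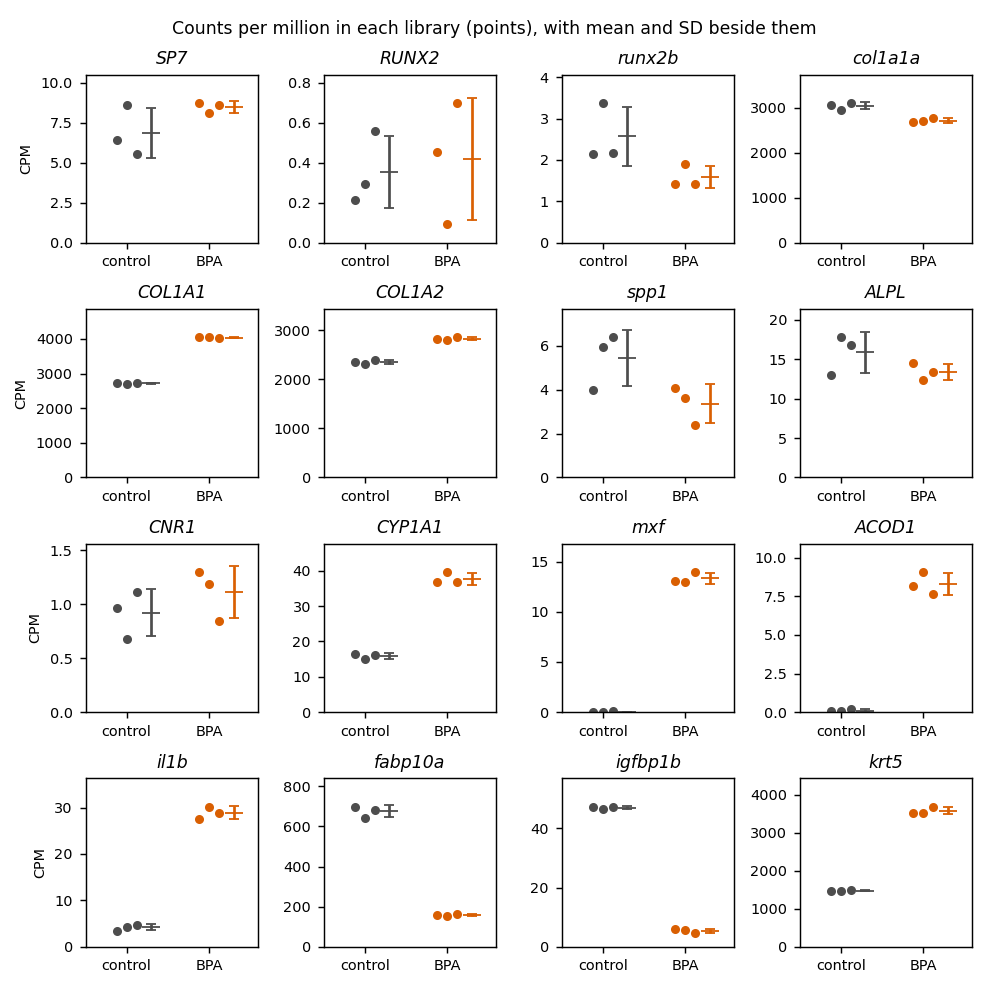
Levels in CPM (linear axis from 0) of 16 genes in each of the 3 control and 3 BPA-exposed libraries (points), with the mean and SD of each group beside them; the panels were chosen after the values were seen. SP7 lay at 6.87 CPM in the control and 8.49 CPM in the exposed libraries, while il1b, krt5 and fabp10a show no overlap between the groups.

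Genes of the osteoblast lineage and bone matrix did not move together. Of 37 tested, 10 rose, 12 fell and 15 did not pass; adjusted over the list alone, 12 were higher and 13 lower. COL1A1 (ENSDARG00000035809) and COL1A2, which encode chains of type I collagen, the main protein of bone matrix, rose from 2715 ± 23.8 to 4037 ± 15.6 CPM and from 2350 ± 34.7 to 2827 ± 30.2 CPM. Their paralog col1a1a fell from 3048 ± 82.7 to 2718 ± 52.0 CPM (adjusted p = 1.32e-05), and whether reads were shared between these paralogs was not tested. SERPINH1 (ENSDARG00000019949), a collagen chaperone gene, rose from 35.8 ± 1.04 to 77.5 ± 3.07 CPM, and another gene of that name (ENSDARG00000075954) did not pass (adjusted p = 0.483). The matrix gene POSTN (ENSDARG00000104267) rose by 0.47 ± 0.02 on the log2 scale, but another gene of that name (ENSDARG00000043806) fell from 164 to 113 CPM. COL12A1 (ENSDARG00000078322), a fibril-associated collagen gene, fell from 724 ± 22.1 to 446 ± 4.88 CPM, but another gene of that name (ENSDARG00000019601) rose from 107 to 129 CPM. The list test gave an adjusted p of 0.60, with a median log2 fold change of -0.05.

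Several osteoblast regulators and markers were low in these sorted cells. SP7 (ENSDARG00000019516) was at 6.87 ± 1.55 CPM in the control and 8.49 ± 0.355 CPM in the exposed libraries (log2 fold change 0.30 ± 0.18 SE, adjusted p = 0.175); without control library 2 its adjusted p was 0.0300. RUNX2 and runx2b, which encode the osteoblast master regulator, were at 0.356 and 2.57 CPM in the controls and 0.417 and 1.59 CPM in the exposed libraries (adjusted p = 0.855 and 0.0839). The osteopontin gene spp1 fell from 5.44 ± 1.29 to 3.37 ± 0.880 CPM (adjusted p = 0.0196), a call lost without control library 2 (0.0701), control library 3 (0.0766) or exposed library 3 (0.156). The alkaline phosphatase gene ALPL was at 15.9 ± 2.57 and 13.4 ± 1.03 CPM (adjusted p = 0.131, or 0.0147 without control library 1). Of the 2 genes named COL10A1, ENSDARG00000054753 was at 212 and 208 CPM (adjusted p = 0.582) and ENSDARG00000101535 at 0.156 and 0.592 CPM (adjusted p = 0.0695). The osteocalcin gene bglap had 0 counts in every library. At 3 counts this allows up to 0.0806 CPM in a control library and 0.0797 CPM in an exposed library, or more if both mates were counted.

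The RANKL-OPG and osteoclast list, which holds the signals and effectors of bone resorption, was higher in the exposed libraries (median log2 fold change 0.50, camera adjusted p = 0.0253; adjusted p = 0.133 with an estimated correlation). Of 15 tested genes 7 rose, 2 fell and 6 did not pass, with the same counts adjusted over the list alone. MMP9, a matrix metalloproteinase gene, rose from 79.9 ± 3.64 to 129 ± 7.25 CPM. SPI1, the transcription factor gene of the myeloid lineage, rose from 4.58 ± 0.891 to 12.7 ± 0.712 CPM, and TCIRG1 (ENSDARG00000105142), a proton pump subunit gene, from 23.5 to 36.2 CPM. CTSK, the collagen-degrading protease gene of osteoclasts, fell from 103 ± 2.83 to 78.5 ± 2.80 CPM. The RANKL gene tnfsf11 was at 0.798 ± 0.555 and 1.42 ± 0.775 CPM (adjusted p = 0.202) and the decoy receptor gene tnfrsf11b at 3.06 ± 1.36 and 4.39 ± 0.0817 CPM (adjusted p = 0.110). Without control library 3 these p values were 0.0255 and 0.00425. Leukocyte markers, which share SPI1 with this list, were also higher in the exposed libraries (median log2 fold change 0.74).

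Endocannabinoid genes gave no list call (median log2 fold change 0.15, camera adjusted p = 0.365). Of 20 tested 5 rose, 1 fell and 14 did not pass, with the same counts adjusted over the list alone. The cation channel gene trpv1 rose from 1.45 ± 0.419 to 5.53 ± 0.368 CPM, the monoacylglycerol lipase gene mgll from 53.3 ± 4.46 to 67.0 ± 4.76 CPM, and a cyclooxygenase gene, PTGS2 (ENSDARG00000004539), from 74.1 to 101 CPM. FABP7 (ENSDARG00000007697), a lipid carrier gene also held by the glial list, fell from 576 ± 9.95 to 167 ± 7.30 CPM. The cannabinoid receptor gene CNR1 was at 0.922 ± 0.221 and 1.11 ± 0.238 CPM (log2 fold change 0.27 ± 0.27 SE, adjusted p = 0.702). CNR2 had 0 counts in each control library and 8, 12 and 0 in the exposed libraries, too few to test.

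In the estrogen and estrogen-related receptor axis 4 of 12 tested genes rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone. The orphan receptor genes ESRRA and esrrd rose from 10.7 ± 1.88 to 18.1 ± 1.90 CPM and from 1.19 ± 0.405 to 3.77 ± 0.797 CPM, and the coactivator gene NCOA3 from 43.4 to 52.4 CPM. The estrogen-related receptor gamma gene esrrgb rose from 0.909 ± 0.0787 to 1.95 ± 0.584 CPM (adjusted p = 0.0241), a call lost without exposed library 2 (0.207). Its paralog ESRRG was at 4.67 and 6.08 CPM (adjusted p = 0.118). The estrogen receptor genes named ESR2, ENSDARG00000016454 and ENSDARG00000034181, had adjusted p of 0.902 and 0.931. ESR1 had 0, 12 and 0 counts in the control and 4, 12 and 2 in the exposed libraries and was not tested. The aromatase gene named CYP19A1 (ENSDARG00000041348) had 0 counts in every library. It was matched to the fixed gene cyp19a1b without its paralog letter, and whether it is that paralog was not tested. The list median was 0.37 and the mean 0.002 on the log2 scale, the mean being pulled down by vtg7, and camera gave an adjusted p of 0.110.

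Of 21 xenobiotic metabolism genes tested, 8 rose, 5 fell and 8 did not pass (9 and 5 adjusted over the list alone), and the list gave no call (median 0.17, camera adjusted p = 0.244). CYP1A1, the classic target of the aryl hydrocarbon receptor, rose from 15.9 ± 0.870 to 37.7 ± 1.72 CPM (adjusted p = 7.87e-13). FOXQ1, a forkhead transcription factor gene, rose from 84.2 ± 3.07 to 262 ± 3.25 CPM, and the sulfotransferase gene sult2st1 from 67.2 to 119 CPM. The intestinal and hepatic gene cyp3a65 fell from 43 ± 5.04 to 16.1 ± 0.842 CPM, and markers of both organs were also lower (medians of -1.08 for liver and -0.88 for intestine). NRF2 and oxidative stress genes were mixed, with 6 of 23 up, 8 down and 9 not past (6 and 9 adjusted over the list alone; median -0.07, camera adjusted p = 0.447). Within this list the glutathione peroxidase gene gpx4a fell from 174 ± 13.5 to 36.0 ± 2.07 CPM, the peroxiredoxin gene prdx1 from 150 to 58.6 CPM and the catalase gene CAT from 102 to 67.0 CPM. The mitochondrial superoxide dismutase gene SOD2 rose from 65.5 to 94.2 CPM.

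The 3 developmental signaling lists were lower. BMP and TGF-beta genes fell as a list (median log2 fold change -0.41, camera adjusted p = 1.51e-05; adjusted p = 0.046 with an estimated correlation), with 18 of 29 lower, 1 higher and 10 not past, also adjusted over the list alone. The growth factor gene TGFB3 fell from 80.0 ± 3.78 to 39.7 ± 1.16 CPM, the matrix gene TGFBI from 262 to 177 CPM, the BMP target ID1 from 109 ± 2.62 to 68.1 ± 2.34 CPM, and the inhibitory SMAD6 (ENSDARG00000031763) from 44.9 to 28.7 CPM. Wnt genes were lower (median -0.17, camera adjusted p = 0.00649; adjusted p = 0.144 with an estimated correlation), with 11 of 23 down, 0 up and 12 not past, also adjusted over the list alone. Among them were the ligand gene WNT11 (133 to 103 CPM), the pathway target AXIN2 (104 to 80.7 CPM), the feedback inhibitor gene NKD1 (50.9 to 37.3 CPM) and SOST (16.4 to 9.10 CPM), a secreted inhibitor of bone formation. Hedgehog genes were lower (median -0.30, camera adjusted p = 0.0033; adjusted p = 0.114 with an estimated correlation), with 7 of 12 down, 0 up and 5 not past, also adjusted over the list alone. SHH, a ligand gene, fell from 5.88 ± 0.596 to 1.27 ± 0.138 CPM, and the receptor and target gene PTCH1 from 32.5 to 20.1 CPM. HHIP, a ligand-binding inhibitor gene, fell from 25.0 to 15.9 CPM. Markers of endothelium (median -0.95), intestine (-0.88) and neural crest and glia (-0.53) were also lower in these libraries.

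Chondrocyte markers were lower beside these, and other matrix genes went both ways. Chondrocyte markers fell in 14 of 22 cases, rose in 1 and did not pass in 7, also adjusted over the list alone (median -0.36, camera adjusted p = 4.90e-04; adjusted p = 0.114 with an estimated correlation). The cartilage collagen gene COL2A1 (ENSDARG00000069093) fell from 210 ± 11.3 to 138 ± 6.23 CPM, hapln1a, which links hyaluronan to aggrecan, from 307 to 193 CPM, and MATN4 from 180 to 118 CPM; COL11A1 (ENSDARG00000026165) rose from 173 ± 4.43 to 306 ± 3.62 CPM. In the extracellular matrix remodelling list 14 of 25 genes fell, 7 rose and 4 did not pass (15 lower and 7 higher adjusted over the list alone). Fibronectin FN1 (ENSDARG00000006526) fell from 369 ± 16.3 to 243 ± 1.70 CPM, col6a1 from 409 to 288 CPM and the membrane metalloproteinase gene MMP14 (ENSDARG00000002235) from 155 to 105 CPM. That list had a median of -0.34, a mean of -0.01 and a camera adjusted p of 0.0416 (lower; adjusted p = 0.325 with an estimated correlation). Its p was 0.0550 and 0.0634 without control libraries 2 and 3, and 0.0698 and 0.0720 without exposed libraries 2 and 3. Tendon and fibroblast markers gave no call (6 of 18 up, 8 down and 4 not past, also adjusted over the list alone; median -0.26, mean -0.05, camera adjusted p = 0.353). The limb and skull mesenchyme genes named PRRX1 fell from 130 to 68.1 CPM (ENSDARG00000033971) and from 91.8 to 53.2 CPM (ENSDARG00000042027), twist1a from 61.4 to 35.9 CPM, and the tendon gene TNMD rose from 27.7 to 51.0 CPM.

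Inflammation genes rose as a list (median log2 fold change 0.73, camera adjusted p = 5.39e-08; adjusted p = 0.046 with an estimated correlation), with 17 of 24 higher, 0 lower and 7 not past, and 18 higher adjusted over the list alone. The interferon regulatory factor gene irf1b rose from 8.27 ± 2.34 to 37.5 ± 2.51 CPM, the chemokine gene cxcl18b from 6.21 ± 0.263 to 19.9 ± 0.662 CPM, and il1b by 2.79 ± 0.14 on the log2 scale (adjusted p = 2.62e-17). Leukocyte markers rose beside them, 12 of 14 higher, 0 lower and 2 not past, also adjusted over the list alone (median 0.74, camera adjusted p = 2.96e-06; adjusted p = 0.046 with an estimated correlation). The macrophage pore-forming gene MPEG1 rose from 7.96 ± 0.792 to 40.7 ± 2.37 CPM, the phagocyte oxidase gene cybb from 7.22 to 21.9 CPM and rac2 from 81.4 to 124 CPM. The share of counts of leukocyte markers was 0.0245% ± 0.000551 in the control and 0.0401% ± 0.0004 in the exposed libraries (SD, n = 3; exact permutation p = 0.1).

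Immediate early and dissociation stress genes also rose, 22 of 30 higher, 3 lower and 5 not past, with 24 higher and 3 lower adjusted over the list alone (median 0.33, camera adjusted p = 1.25e-05; adjusted p = 0.046 with an estimated correlation). The early response gene FOS (ENSDARG00000031683) rose from 113 ± 5.33 to 228 ± 5.23 CPM, ier2b from 112 to 208 CPM, the phosphatase gene DUSP2 from 49.1 to 101 CPM and the cytokine feedback gene SOCS3 (ENSDARG00000025428) from 54.9 ± 0.879 to 123 ± 3.76 CPM. These transcripts are known to rise when tissue is dissociated into cells. Leukocyte markers (median 0.74) were also higher.

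Cholesterol synthesis genes rose as a list (median 0.49, camera adjusted p = 2.66e-04; adjusted p = 0.046 with an estimated correlation), with 15 of 21 higher, 1 lower and 5 not past, also adjusted over the list alone. HMGCS1, an early enzyme of the pathway, rose from 45.0 ± 3.11 to 77.8 ± 5.17 CPM, and the later enzyme genes SQLE (ENSDARG00000079946) and EBP from 2.22 to 6.88 CPM and from 4.47 to 11.7 CPM. The gene of their transcriptional regulator, srebf2, rose from 79.8 ± 0.672 to 102 ± 3.11 CPM. Epidermis markers (median 0.42; adjusted p = 0.114 with an estimated correlation) and skeletal muscle markers (median 0.28; adjusted p = 0.35 with an estimated correlation) were also higher. PPAR and lipid handling genes were mixed, 7 of 24 up, 8 down and 9 not past, also adjusted over the list alone (median 0.04, camera adjusted p = 0.822). CEBPB, a transcription factor gene of adipocytes and of inflammation, rose from 282 ± 16.3 to 451 ± 8.44 CPM. The lipase gene LPL, its inhibitor ANGPTL4 and the apolipoprotein gene apoeb fell, from 258 to 181, from 228 to 169 and from 1085 to 852 CPM.

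Cell cycle genes gave no list call (8 of 30 up, 8 down and 14 not past, or 8 and 9 adjusted over the list alone; median 0.04, camera adjusted p = 0.922). The replication helicase genes MCM2, MCM3 and MCM5 fell by 0.34, 0.43 and 0.30 on the log2 scale, while the proliferation marker mki67 rose from 79.7 ± 5.77 to 107 ± 1.74 CPM. Of 24 p53 and apoptosis genes 8 rose, 5 fell and 11 did not pass, also adjusted over the list alone (median 0.08, camera adjusted p = 0.822). The cell cycle inhibitor gene cdkn1a fell from 36.0 ± 2.55 to 17.0 ± 1.43 CPM and rps27l from 70.5 to 53 CPM, and the DNA damage response gene GADD45A (ENSDARG00000043581) rose from 18.9 to 27.9 CPM. Of 24 unfolded protein response genes 1 rose, 9 fell and 14 did not pass, also adjusted over the list alone (median -0.05, camera adjusted p = 0.164). The endoplasmic reticulum chaperone genes HSPA5, HSP90B1 and CALR (ENSDARG00000076290) fell from 269 to 233, from 160 to 138 and from 65.4 to 42.1 CPM, and the disulfide isomerase gene PDIA3 from 221 to 186 CPM.

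Cytosolic ribosomal protein genes fell by small amounts, 77 of 82 lower, 2 higher and 3 not past, with 78 lower and 2 higher adjusted over the list alone (median -0.22, camera adjusted p = 2.22e-11; adjusted p = 0.35 with an estimated correlation). RPL12 fell from 2732 ± 29.1 to 1761 ± 56.5 CPM, rps20 by 0.60 and RPLP1 by 0.55 on the log2 scale, and RPLP0 from 7080 to 5322 CPM. The share of counts of this list was 16.0% ± 0.355 in the control and 13.4% ± 0.16 in the exposed libraries (SD, n = 3; exact permutation p = 0.1). One of the 2 genes that rose, rps19bp1, encodes a ribosomal protein's binding partner and entered the list through its name. Mitochondrially encoded genes were mixed, 5 of 13 up, 5 down and 3 not past, or 6 and 5 adjusted over the list alone (median 0.06, camera adjusted p = 0.897). MT-CO2 fell from 9319 ± 266 to 7549 ± 190 CPM, and the complex I genes MT-ND5, mt-nd4l and MT-ND2 rose by 0.28, 0.27 and 0.19 on the log2 scale.

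Markers of internal organs were lower in the exposed libraries. Of 17 liver markers 15 fell, 0 rose and 2 did not pass (15 lower and 1 higher adjusted over the list alone; median -1.08, camera adjusted p = 1.41e-09; adjusted p = 0.046 with an estimated correlation). The plasma protein genes apoa2, serpina1 and FGB fell from 1855 ± 34.5 to 517 ± 6.37 CPM, from 346 to 89.8 CPM and from 160 to 45.5 CPM, and fabp10a by 2.09 ± 0.04 on the log2 scale. Of 17 intestine markers 11 fell, 3 rose and 3 did not pass, also adjusted over the list alone (median -0.88, camera adjusted p = 2.53e-04; adjusted p = 0.046 with an estimated correlation). The apolipoprotein gene apoa1b fell from 5500.4 ± 144 to 1541 ± 12.8 CPM, apoa4b.1 from 162 to 56.5 CPM, the fatty acid carrier gene FABP2 from 53.8 to 27.4 CPM and the chitinase gene chia.2 from 22.1 to 9.74 CPM. Exocrine pancreas markers fell in 9 of 13 cases and rose in 4, also adjusted over the list alone (median -0.41, camera adjusted p = 0.0253; adjusted p = 0.383 with an estimated correlation). Among these digestive enzyme genes, prss1, CPA1 (ENSDARG00000021339) and ctrl fell from 1033 to 501, from 820 to 420 and from 364 to 138 CPM, and prss59.1 rose from 58.0 ± 4.99 to 205 ± 5.64 CPM.

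Neural, sensory and vascular markers were lower as well. All 15 called photoreceptor genes of 18 tested fell, also adjusted over the list alone (3 not past; median -0.94, camera adjusted p = 9.76e-09; adjusted p = 0.046 with an estimated correlation). They included the cone transducin gene GNAT2 (151 ± 3.17 to 63.6 ± 1.98 CPM), the cone arrestin gene ARR3 (98.4 to 41.3 CPM), GNGT2 (134 to 65.3 CPM; ENSDARG00000103543) and the blue opsin gene opn1sw2 (82.3 to 40.2 CPM). Neural crest and glia markers fell in 9 of 14 cases, rose in 1 and did not pass in 4, also adjusted over the list alone (median -0.53, camera adjusted p = 1.94e-04; adjusted p = 0.046 with an estimated correlation). The glial glutamine synthetase gene GLUL (ENSDARG00000099776) fell from 736 ± 3.16 to 207 ± 8.31 CPM, the glutamate transporter gene SLC1A2 (ENSDARG00000102453) from 744 to 254 CPM and the intermediate filament gene GFAP from 31.5 to 9.54 CPM. Endothelial markers fell in 11 of 15 cases, rose in 0 and did not pass in 4 (12 lower adjusted over the list alone; median -0.95, camera adjusted p = 3.36e-06; adjusted p = 0.046 with an estimated correlation). The vascular receptor gene kdrl fell from 36.6 ± 3.01 to 18.5 ± 0.263 CPM, plvapb from 19.1 to 5.73 CPM, EGFL7 from 20 to 9.45 CPM and the cadherin gene cdh5 from 13.4 to 5.90 CPM. Neuron markers fell in 10 of 18 cases, rose in 1 and did not pass in 7, also adjusted over the list alone (median -0.21, camera adjusted p = 0.0416; adjusted p = 0.144 with an estimated correlation). The synaptic gene SNAP25 (ENSDARG00000058117) fell from 41.4 to 27.6 CPM, GNG3 from 25.4 to 17.4 CPM and the microtubule regulator gene STMN2 (ENSDARG00000033234) from 35.2 to 25.2 CPM, while STMN1 (ENSDARG00000004169) rose from 87.2 to 111 CPM. The neuron list's p was 0.0531 and 0.0550 without control libraries 1 and 2 and 0.0705 and 0.0662 without exposed libraries 2 and 3.

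Markers of muscle, epidermis, blood and pigment cells were higher. Of 20 skeletal muscle genes 15 rose, 4 fell and 1 did not pass (16 and 4 adjusted over the list alone; median 0.28, camera adjusted p = 0.00124; adjusted p = 0.35 with an estimated correlation). The myosin heavy chain genes myhz1.1, myhz2 and smyhc1 rose from 1447 ± 40.2 to 2956 ± 55.2, from 939 to 1662 and from 384 to 836 CPM, and myhz1.2 by 1.34 ± 0.03 on the log2 scale. Of 17 epidermis genes 12 rose, 1 fell and 4 did not pass, also adjusted over the list alone (median 0.42, camera adjusted p = 4.31e-05; adjusted p = 0.114 with an estimated correlation). The keratin genes krt91, krt4 and krt17 rose from 2272 ± 30.0 to 6615 ± 58.2, from 3359 to 6029 and from 790 to 1637 CPM. Of 11 erythroid genes 6 rose, 0 fell and 5 did not pass (7 higher adjusted over the list alone; median 0.72, camera adjusted p = 0.00148; adjusted p = 0.0735 with an estimated correlation). The globin gene hbae3 rose from 370 ± 6.01 to 548 ± 7.22 CPM, the heme synthesis gene alas2 from 7.22 to 13.9 CPM, and the anion exchanger genes named SLC4A1 from 6.25 to 20.1 CPM (ENSDARG00000012881) and from 28.9 to 48.4 CPM (ENSDARG00000024560). Of 14 pigment cell genes 6 rose, 0 fell and 8 did not pass, also adjusted over the list alone (median 0.28, camera adjusted p = 0.0376; adjusted p = 0.144 with an estimated correlation). The pteridine synthesis gene gch2 and the melanin synthesis genes TYRP1 (ENSDARG00000056151) and TYR rose from 422 to 519, from 37.9 to 53.9 and from 4.04 to 7.35 CPM, and GPNMB from 14.7 to 18.9 CPM. The pigment cell list's p was 0.0696 without control library 1 and 0.0557 without exposed library 3, and that of GPNMB 0.0586 without control library 3 and 0.0992 without exposed library 2. Lens genes gave no call, with 1 of 14 higher (crybb1l1, 8.33 to 12.3 CPM), 0 lower and 13 not past, also adjusted over the list alone (median 0.23, camera adjusted p = 0.0934). That p was 0.0151 without control library 2 and 0.0338 without exposed library 1. Of 6 otic vesicle genes 2 fell, 0 rose and 4 did not pass, also adjusted over the list alone (median -0.22, camera adjusted p = 0.126). The otolith gene stm fell from 145 ± 2.03 to 115 ± 5.86 CPM. The proton channel gene OTOP1 fell from 4.96 to 3.31 CPM (adjusted p = 0.0416), a call lost without control libraries 2 and 3 (0.0725 and 0.0997) or exposed libraries 1 and 2 (0.130 and 0.203).

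**Figure D2:**
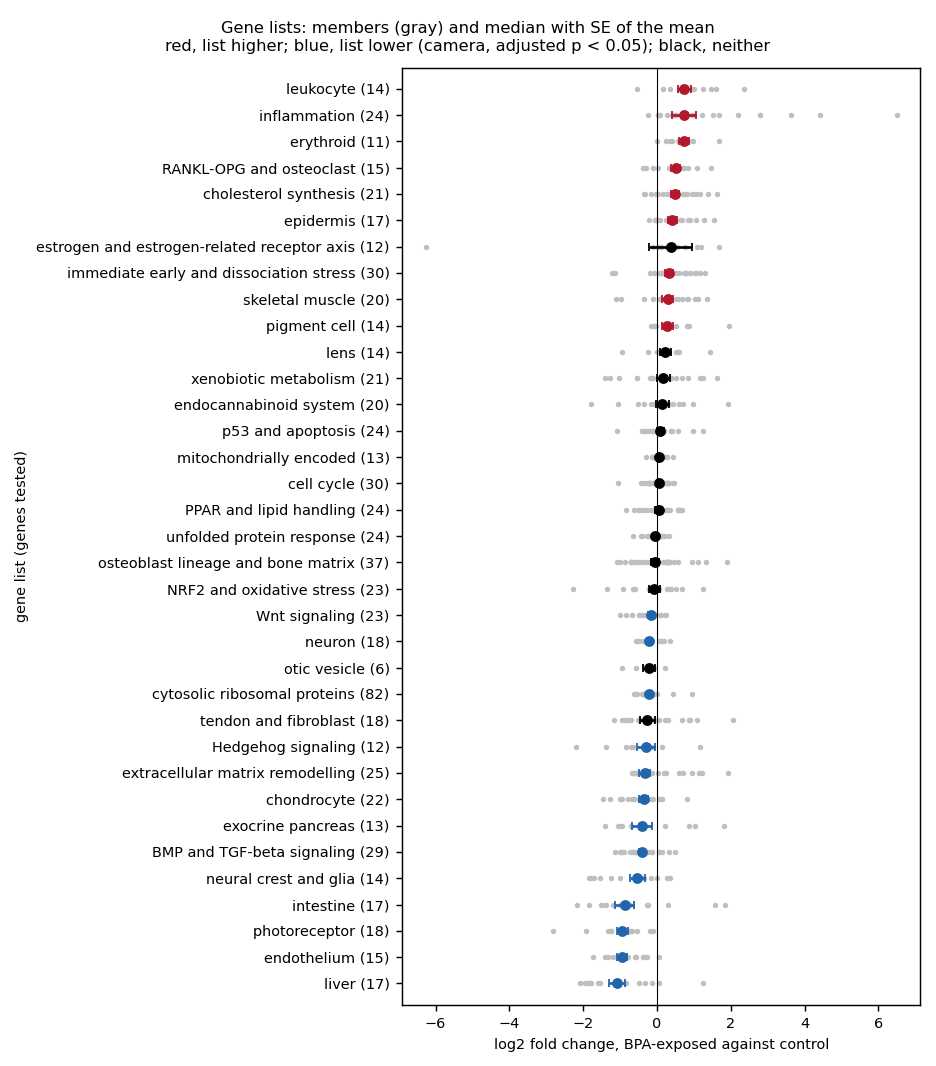
Log2 fold change of BPA-exposed against control libraries for each tested member (gray) of the 35 gene lists, with the list median and the SE of its mean; red lists were higher and blue lists lower by camera at an adjusted p of 0.05, and black lists passed neither way. Leukocyte, inflammation and erythroid lists lie at the top and liver, endothelium and photoreceptor lists at the bottom.

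The sorted libraries held transcripts of several cell types, and their shares differed between the groups. Osteoblast and bone matrix genes held 1.37% ± 0.0185 of control counts and 1.55% ± 0.00621 of exposed counts (SD, n = 3). Skeletal muscle markers held 5.67% and 6.72%, and epidermis markers 1.73% and 2.89%. Liver markers held 0.792% and 0.463%, intestine markers 0.583% and 0.170%, exocrine pancreas markers 0.407% and 0.257%, and neural crest and glia markers 0.269% and 0.114%. Mitochondrially encoded genes held 6.39% ± 0.236 and 5.92% ± 0.2. Each of these differences had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The shares of the tendon and fibroblast list and of the p53 and apoptosis list had an exact p of 0.4. The 10 most abundant genes held 11.6% of control and 11.7% of exposed counts. Shares can rest on a few genes and do not measure cell numbers. Most of the intestine share came from apoa1b, at 5500 CPM in the control and 1541 CPM in the exposed libraries. The osteoblast and bone matrix share rose although 12 of the 37 tested genes of that list fell and 10 rose.

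**Figure D3:**
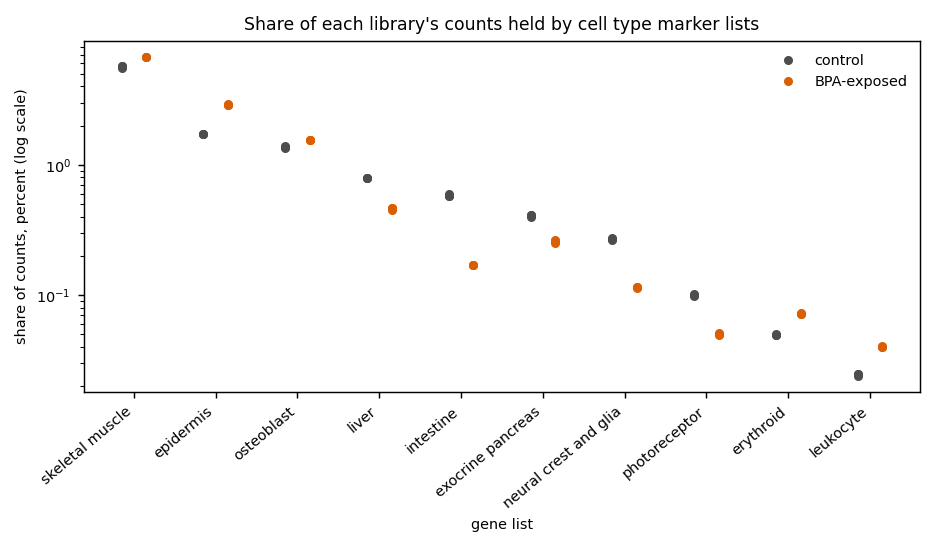
Share of each library's counts (percent, log axis) held by 10 cell type lists in the 3 control (gray) and 3 BPA-exposed (orange) libraries, each library drawn as 1 point. Intestine markers, mostly apoa1b, lie near 0.583% in the control and 0.170% in the exposed libraries, and epidermis markers near 1.73% and 2.89%.

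Camera called 22 of the 35 lists, 9 higher and 13 lower, and 10 of them with a correlation estimated from the data. The labels do not state that libraries came from separate pools, so these p values may measure technical spread, and the small values above carry over to other fish only as far as the libraries are independent.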

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

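Halved counts and leaving out ribosomal protein and mitochondrially encoded genes were tests chosen after the result was seen; the other alternatives were fixed before. The number of called genes stayed within 1.5 times of 8213 under 3 other scalings (8179 to 8211), DESeq2 (7882, with 2520 adjusted p values not given), limma-voom (8395), no filter (8408) or a stricter one (8003), no robust estimation (8205), an adjusted p of 0.1 (9502), the smaller gene set (8115) and leaving out 1 library (6712 to 8063). The other scalings called 8139 to 8191 of the same genes. Halved counts (8388) scale every gene and library alike and say nothing of stability. A 2-fold minimum left 1926 genes, 1185 higher and 741 lower (61.5% higher against 51.8%), because it removes small changes.

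With an estimated correlation 10 lists passed, all at the same camera adjusted p of 0.046. Adjusted p values of the 12 lists that lost their call were 0.133 for RANKL-OPG, 0.144 for Wnt, neuron and pigment cell, 0.114 for Hedgehog, chondrocyte and epidermis, 0.325 for extracellular matrix, 0.35 for muscle and ribosomal proteins, 0.0735 for erythroid and 0.383 for exocrine pancreas. The fry test, which compares a list with no other genes, added estrogen (0.0103), xenobiotic (0.00027), NRF2 (0.025), unfolded protein response (0.00749), PPAR (0.0137), lens (0.025), tendon (0.000443) and otic vesicle (0.00376). Without a filter the lens list passed (0.0327) and the cell cycle list turned lower (0.971), both from a wider set of genes. Scaling by relative log expression or by library size only changed 0 list calls. The 50 most abundant genes differed by 0.9 percentage points between the groups, more than the top 10.

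Leaving out 1 library moved the adjusted p of the extracellular matrix list between 0.0355 and 0.072, neuron between 0.026 and 0.0705, pigment cell between 0.029 and 0.0696 and lens between 0.0151 and 0.151. The cell cycle list (0.692 to 0.898) and the mitochondrially encoded list (0.672 to 0.931) changed direction without passing. Genes that did not pass and changed sign were RUNX2 (log2 fold change -0.0535 by limma-voom, -0.39 to 0.71 with 1 library left out), COL10A1 (ENSDARG00000054753, -0.0599 to 0.0096) and the ESR2 genes ENSDARG00000016454 (-0.48 to 0.0946) and ENSDARG00000034181 (-0.16 to 0.20). OTOP1 did not pass by DESeq2 (adjusted p = 0.0564) and tnfrsf11b passed by limma-voom (0.0337). The cause was not tested in these cases.

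With the replicate number as a block, 8164 genes were called, and the extracellular matrix (0.0797), neuron (0.0584) and exocrine pancreas (0.0553) lists did not pass; it changed no other list and no named gene. Libraries of the same number did not deviate together (r across genes -0.013, -0.004 and 0.012), and not every library correlated best with its own number, so the numbers give no pairing.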

Other observations

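The tests of a purer sort and of halved counts, and the gene families, were chosen after the result was seen, and the rules by which the leukocyte, stress, liver and halved-count tests are read were changed after their first values were known, each towards leaving the explanation open. Gene families were picked from 35 symbol patterns that were looked at, so their counts stand without a claim of enrichment; their directions held under the 3 other scalings with counts that moved by at most 1, and the single crystallin call was lost with library size only. Of all tested genes, 20.1% were called higher and 18.7% lower. The immune families described here held larger shares of higher genes, but of 46 genes whose symbols begin with il, interleukin genes among them, 12 rose and 4 fell. Of 5 mx GTPase genes 4 rose and 1 did not pass, and of 7 Toll-like receptor genes, which sense microbial molecules, 5 rose and 2 did not pass. Of 12 CXC chemokine genes 8 rose and 3 fell, with cxcl18a.1 up from 3.54 ± 1.4 to 13.3 ± 1.1 CPM (SD, n = 3) and CXCL12 down from 249 to 152 CPM. Of 20 CC chemokine genes 10 rose and 1 fell, and ccl19b rose from 2.31 to 20 CPM. Leukocyte markers were also higher, 12 of 14 tested (median log2 fold change 0.74). In all, 21 genes had 0 counts in every control library and were called higher, against 1 with 0 counts in every exposed library and called lower.

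Of 5 her4 genes, which are Notch targets of neural progenitors, 4 fell and 1 did not pass (her4.4 from 11.2 to 1.98 CPM), while neural crest and glia markers (median log2 fold change -0.53) and neuron markers (-0.21; adjusted p = 0.144 with an estimated correlation) were also lower. Of 18 keratin genes 11 rose and 2 fell, and krt1-19e rose from 4282 ± 173 to 11391 ± 147 CPM. The epidermis markers, some of which are keratins, were also higher (median 0.42, camera adjusted p = 0.114 with an estimated correlation). Of 47 HOX genes, which pattern the body axis, 11 fell and 3 rose, with HOXB13 down from 7.65 to 1.96 CPM and hoxa13a from 3.99 to 1.45 CPM. Of 24 ugt genes 9 fell and 1 rose, and of 30 cyp2 genes 12 fell and 5 rose, while liver markers were also lower (median -1.08); the fixed xenobiotic metabolism list, with 8 higher and 5 lower of 21, gave no call (median 0.17). Of 20 crystallin genes of the crygm2d group 1 rose and 19 did not pass.

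Inflammation genes rose in the exposed libraries, 17 of 24 by the per-gene test. Stronger dissociation stress in the exposed tubes stays open: stress genes rose as a list, with a median log2 change of 0.329. The median of the whole inflammation list, 0.73, lay 0.401 above it. The SE used here, 0.347, is that of the difference of the list means over genes, not of the medians. By that SE the medians lay within 2 SE, but the means, 1.377 for inflammation and 0.372 for stress, did not. Genes of a list do not vary independently, so neither comparison decides. More leukocytes in the exposed sorts stay open too: leukocyte markers had a median of 0.743, close to that of the inflammation list. The bounds written beforehand would have excluded both (0.537 at 2 SE above the stress median and 1.11 above the leukocyte median, against 1.21 for the 17 called genes), but they compared whole lists with called genes alone and were therefore wrong. A response of the sorted cells to BPA, dissociation stress and a few more phagocytes passing the GFP gate cannot be told apart here, since no value separates cells.

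Liver transcripts fell in the exposed libraries. The rule for a purer sort that removed every other cell type alike named muscle, epidermis or neuron markers as what could speak against it. Epidermis markers met it, with a median of 0.417 (0.175 at 2 SE below), and muscle markers had a median of 0.28. With an estimated correlation, however, these lists did not pass (camera adjusted p = 0.114 and 0.35), and neuron markers fell (median -0.21). Leukocyte markers rose by 0.743 (0.373 at 2 SE below, camera adjusted p = 0.046 with an estimated correlation). They were not named in the rule, and their rise may be a response of the sorted cells. The share of counts of epidermis markers rose from 1.73% ± 0.00486 to 2.89% ± 0.0323, and that of muscle markers from 5.67% ± 0.0867 to 6.72% ± 0.0482 (SD, n = 3). These rises argue against a sort that removed every other cell type alike, unless the sorted cells themselves raised these transcripts. Whether the exposed sort was purer in another way is not settled. Fewer liver cells or less free liver RNA stay open: 100% of the 15 liver markers at 10 CPM or more fell, from RBP4 at 3473 CPM to CP at 31.1 CPM in the controls. Their changes ranged from -2.09 to -0.13, which goes against such a loss as the whole cause if liver alone makes these transcripts, since it would lower them by a like amount. What keeps it open is that markers also made elsewhere would fall by less, which was not tested, and that 0 of the 15 were called higher, where markers called higher were set beforehand as what would speak against it. A fall of most of these markers was at first read as fitting this explanation, and that reading was dropped after the value was known. A change within liver cells was not tested either. The liver list shares 0 of its 17 genes with the other lists. A GFP gate is meant to remove hepatocytes, but liver transcripts were present in the sorted libraries. In the controls fabp10a was at 675 CPM and SP7 at 6.87 CPM.

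A large share of genes passed with 3 libraries per group. The 6 libraries allow 10 splits, too few for a share under 0.05. The real split, the only 1 of the 10 with as many genes, called 8213 genes by edgeR. The highest other called 0 by edgeR (264 at an unadjusted p under 0.05, 0 by limma-voom). Every other split mixes the arms, so a difference between the arms widens the spread there. The 0 calls therefore say nothing of the cause of that difference. Counting both mates stays open: a count that halving keeps within 1.5 times (8388 called) was first taken to exclude it, which was wrong, since halving scales every gene and library alike and tests nothing. Parental haplotype blocks that differ between the arms were looked for among the 241 called genes with at least a 4-fold change that could be placed. Of these, 6.22% had another of them, with a different name stem and changed in the same direction, among their 5 neighbors on either side. The median was 8.71% in 100 random sets matched on mean expression (4.56% to 14.5%). This share shows no excess of neighbors, but it cannot exclude blocks. Clone names with the same prefix counted as 1 stem, so adjacent genes with such names could not pair, and the random sets were not matched for clone names. The haplotype explanation was narrowed to blocks after the value was seen. Scattered parental variants, different parents and libraries drawn from 1 pool per arm were not tested.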
